A study of Mus musculus with 12 samples.

How the data were processed

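RNA sequencing had been run on 12 libraries of differentiated 3T3-L1 adipocytes, 6 electroporated with a control siRNA and 3 with each of 2 siRNAs against Zfp407. Per the labels' protocols, 0.75 nmol of siRNA was delivered 2 days after differentiation, total RNA was purified on silica columns after homogenisation on a shredder column, and libraries were made with standard Illumina protocols. Whether the libraries keep strand information is not given in the sources used here. Per the series' design text, each library came from its own electroporation. The p-values below therefore measure the spread between electroporations of 1 cell line, and in the knockdown arm also any difference between the 2 siRNAs. They treat the knockdown libraries as replicates of 1 treatment, although these are 3 libraries of each of 2 siRNAs.

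The deposited data were 1 table of genes, with an FPKM value for each library (fragments per kilobase of transcript, scaled to the number of mapped fragments), made by the authors before deposit. Per the file headers, the same table holds the authors' FPKM of each arm, a log2 fold change, a test statistic, and a p-value and q-value for all Zfp407 siRNA libraries against the control libraries. The submitters' processing notes name TopHat2 2.0.5, Bowtie2 2.0.0.7, SAMtools 0.1.18.0 and Cufflinks 2.0.2, without saying in which order or with which settings they were run. The genome build and the annotation are not given in the sources used here. Of the rows of protein-coding genes that also stand in the GENCODE M21 annotation of GRCm38, 99.6% overlapped that gene's position and 62.7% shared its start or its end within 1 base, and coordinates are given here as positions on that build, counted from 1. Each was taken from the table's own locus column. A row's locus can span several overlapping genes, whose reads the authors' estimation had to divide. Several genes named below have such rows, with 8 rows at the locus of Pfkfb1, 8 at that of Acss2, 5 at that of Stx8 and 4 at that of Cav1. This is not repeated for each gene.

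The table had 39248 rows. Of these, 3036 carried no gene name and 629 named several genes, and both kinds stayed in the tests but could not stand for a single gene. Genes were named as the table names them, and protein-coding symbols were taken from GENCODE M21. Rows were sorted by name into snoRNA names, other short-RNA names (such as U6, microRNA or mitochondrial tRNA names), protein-coding symbols and all others. Some rows are listed at exactly 0 in 1 library and above 0 in others, which in a table without counts can be a failed estimate. For AL662835.1, such a row, the value of each library is given below. For other such rows they are not all given.

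The control columns carry the number of their sample. The 6 knockdown columns carry a number from 1 to 6 and no mark of which of the 2 siRNAs was used, so each knockdown library was used as a member of 1 arm of 6 and no siRNA was assigned to it. The design fixed before the data were examined had 3 groups with a contrast for each siRNA, a test of the difference between the siRNAs, an overlap and a correlation of the 2 siRNA effects, and list tests per siRNA. None of these could be run. The comparison reported is the alternative written at the same time, 6 libraries against 6 in a fit with 2 groups.

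Sequencing depth is unknown in absolute terms, since FPKM values hold no read totals. In low rows (mean FPKM above 0 and under 0.5) the values of 2 libraries have a most frequent ratio, which is what 1 read is worth in each. By this ratio, the depths of the libraries lay between 0.88 and 1.16 of that of control library 1. The summed FPKM ran from 2772929 to 3748488 per library. The worth of 1 read was also compared between sets of libraries, in low rows whose values were whole multiples of a smallest value within a tolerance of 2%. Differences were counted from the most frequent difference, and rows that differed by 0.5 or more on the log2 scale were left out. Within an arm it was fixed: it differed by more than 0.01 on the log2 scale in 0 of 87 rows between odd- and even-numbered control libraries and in 1 of 97 rows between odd- and even-numbered knockdown libraries. Between the arms it differed in 161 of 467 rows (34.5%), with a median size of 0.163 on the log2 scale among those and a 90th percentile of 0.241 over all 467 rows. The authors' values thus carry a term that belongs to a whole arm, which the spread between libraries does not cover and no permutation of libraries can show. Changes smaller than about this size in single rows cannot be told apart from it, and larger differences, left out here, were not sized. A test against a minimum fold of 1.2 was therefore added.

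Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), over the 14706 rows with a mean FPKM of at least 1 across the 12 libraries, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. For Zfp407 and Slc2a4 an exact permutation test over all divisions of the 12 libraries into 6 and 6 was run in Python 3.11.15 with numpy 2.4.6. The method was tested on simulated data drawn from the means and spreads of the 14706 rows. Changed genes and list members were drawn from rows with a mean FPKM of at least 5, so recovery in lower rows was not measured. Of genes changed 1.2-fold, 38.8% of 67 were recovered. Of genes changed 1.5-fold, 89.6% of 67 were recovered, and of genes changed 2-fold, 93.9% of 66. Among all other rows 9 were called. A simulated list of genes shifted together was called and 0 of 20 unshifted lists were. Simulated genes were independent of each other and held no arm-wide term. In the real lists the estimated correlation between genes reached 0.73, for mitochondrially encoded transcripts. These counts therefore do not give the rate of false calls among the real rows or lists.

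Beforehand, 30 gene lists were fixed. The 27 with at least 5 members tested were compared with all other rows by limma's camera with a preset correlation between genes of 0.01, adjusted over the lists. Camera was repeated with the correlation estimated from the residuals of each list, and fry was run beside it. Genes whose only row names several genes were not counted as tested.

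The rule for named genes was fixed at the same time. It names Zfp407 and Slc2a4, the 12 largest rises and the 12 largest falls past the threshold with a mean FPKM of at least 5, leaving out names of Gm with digits, names ending in Rik and names starting with Mir, Snor, Scarna, Rnu or n-R, up to 4 members with the smallest p of each list called and of 4 lists in any case, and the 2 most abundant members of each list of cell type markers. Its condition on both single siRNAs, and its part on genes that differ between the siRNAs, could not be applied. Name patterns were read without regard to case. These patterns let through U6 and a snoRNA name of another form, and rows named after genomic clones. Because such rows filled all of the places among the rises, the same rule was run over protein-coding symbols alone, a choice made after the values were seen. The values of 2 genes that the rule names are not reported here. Other genes named in the text were chosen after their values were seen and are marked so.

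Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter on low values, a filter at a mean FPKM of 5, centring each library on its median, quantile normalization, robust eBayes, array weights, leaving out each of the 12 libraries in turn, and the other list tests. Added after the data were seen were a block by the number in the column name, protein-coding rows alone, leaving out rows the authors marked FAIL (501 of the rows tested), and limma's treat with a minimum fold of 1.2. Figures were drawn with matplotlib 3.10.9.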

Results

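The series measured mRNA by sequencing in 3T3-L1 adipocytes, a mouse line of fibroblast-like preadipocytes that differentiates into fat-storing cells in culture. The cells received either a control siRNA (6 libraries) or an siRNA against Zfp407, which encodes a zinc finger protein (3 libraries with each of 2 siRNAs, treated as 1 arm of 6 because the table does not mark the siRNA of a column). The series title names insulin-stimulated glucose uptake and the mRNA of the glucose transporter GLUT4 as the subject. Summed FPKM ran from 2772929 to 3748488 per library, and no 2 libraries of an arm held the same values, the highest correlation between 2 of them being 0.981 across rows. The share of summed FPKM on the mitochondrial chromosome was 23.7% ± 1.03 (SD, n = 6) in control and 24.97% ± 4.41 (SD, n = 6) in knockdown libraries, with 32.8% in knockdown library 6 and at most 26.3% in every other library.

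Zfp407 (XLOC_015907, chromosome 18, 84128027 to 84591578 on GRCm38) was lower in all 6 knockdown libraries than in any control library. Its FPKM was 2.73, 3.16, 2.798, 2.92, 2.71 and 2.70 in control libraries 1 to 6, and 2.13, 1.93, 1.79, 1.65, 1.604 and 1.62 in knockdown libraries 1 to 6. The means were 2.84 ± 0.178 and 1.79 ± 0.208 (SD, n = 6 each), 36.9% lower in the knockdown arm. The log2 fold change was −0.46 (SE 0.06, limma adjusted p = 8.0e-05), and the exact permutation test gave p = 0.00216, two-sided, the smallest it can give. In the authors' deposited table, the log2 fold change of Zfp407 was −0.77 with a q-value of 0.0734. With the filter at a mean FPKM of 5 the gene was not tested.

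Slc2a4 (XLOC_005601, chromosome 11, 69935796 to 69948224), the gene of GLUT4, fell to a smaller extent. Its FPKM was 103 ± 2.77 in control and 88.5 ± 8.19 in knockdown libraries (SD, n = 6 each), a mean 13.9% lower. All 6 knockdown libraries lay below the control mean, and 5 of them below the lowest control library (99.3), while knockdown library 4 reached 101.9. The log2 fold change was −0.22 (SE 0.06, limma adjusted p = 0.00853; exact permutation p = 0.00866, two-sided). Against a minimum fold of 1.2 the change of Slc2a4 did not pass (adjusted p = 1), and its size is below the 90th percentile of the difference between arms in the worth of 1 read, measured in low rows (0.241). That percentile leaves out rows with differences of 0.5 or more. In the authors' deposited table, Slc2a4 had a log2 fold change of −0.22 and an unadjusted p-value of 0.329. The Slc2a4 row shares its locus with Ybx2, a neighbour listed in the same region.

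**Figure D1:**
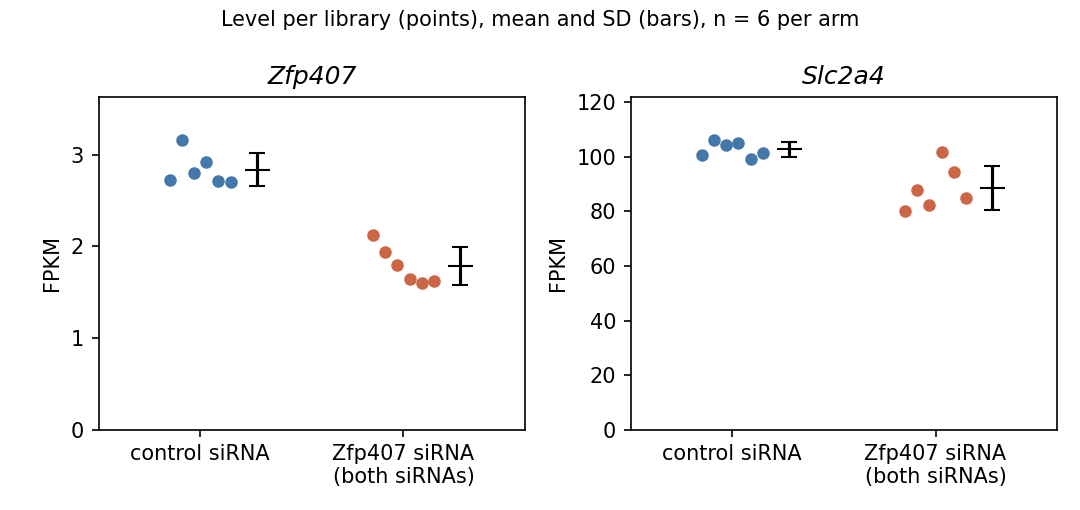
FPKM of Zfp407 (left) and Slc2a4 (right) in each of 6 control siRNA and 6 Zfp407 siRNA libraries (points), with the mean and SD (bar) beside each arm, on axes that start at 0. Zfp407 runs from 2.70 to 3.16 in control and from 1.604 to 2.13 in knockdown libraries, and Slc2a4 from 99.3 to 106 and from 80.2 to 102.

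Across the table, 5360 of 14706 rows differed between the arms, 3648 lower and 1712 higher in the knockdown libraries, a share of 68.1% lower. Most changes were small: the median size of the log2 fold change among called rows was 0.30. The arms did not overlap in 2862 rows (19.5%), where a random division of the libraries gives 0.216%. The term that the authors' values carry for a whole arm can also separate the arms. The excess therefore does not measure changed RNA alone. Without knockdown library 6, which had the highest mitochondrial share, 5050 rows were called. With each library centred on its median, 5453 rows were called, 3146 lower and 2307 higher (57.7% lower), and against a minimum fold of 1.2, 856 rows remained, 543 lower and 313 higher. The authors' deposited table marks 302 rows as significant, 219 lower and 83 higher. Of the 269 of these that were tested here, 267 were called, each with the sign of the authors' deposited table.

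The largest falls among protein-coding genes were those of Apoo and Ndufa1, which both encode mitochondrial proteins. Apoo, which encodes a protein of the mitochondrial cristae organising complex, fell from 37.3 ± 2.60 to 6.75 ± 0.973 FPKM (SD, n = 6 each; log2 fold change −2.31, SE 0.08, adjusted p = 7.6e-10). Ndufa1, a subunit of respiratory complex I, fell from 238 ± 25.02 to 55.4 ± 8.81 FPKM (log2 fold change −2.09). Chmp6, a component of the endosomal sorting machinery, fell from 27.6 ± 3.64 to 8.16 ± 0.988 FPKM (log2 fold change −1.64), and Stx8, an endosomal membrane fusion protein, from 39.5 ± 2.95 to 14.2 ± 0.979 FPKM (log2 fold change −1.41). The others of the 12 largest falls were BC017158, Tbcd (a tubulin folding cofactor), Art3, Aarsd1, Coq4 (coenzyme Q synthesis), Hdhd3, Bbs5 and Ndufs4, another complex I subunit, and the 12 log2 fold changes ran from −2.31 to −1.20. The arms did not overlap for any of the 12, and 9 of them are marked significant in the authors' deposited table. The ranking held only rows whose symbol is protein-coding in the annotation used, so genes listed under other symbols could not enter it. Hbxip, left out for that reason, fell from 39.1 ± 3.38 to 12.4 ± 1.37 FPKM (log2 fold change −1.58, adjusted p = 2.0e-08). Each of these changes passed against a minimum fold of 1.2.

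The largest rises among protein-coding genes were smaller, with log2 fold changes from 0.74 to 1.47. Trib1, a pseudokinase gene, rose from 2.78 ± 0.251 to 9.47 ± 0.984 FPKM (SD, n = 6 each; log2 fold change 1.47, SE 0.07, adjusted p = 1.8e-08). Pygl, the liver form of glycogen phosphorylase, rose from 2.47 ± 0.285 to 8.40 ± 1.51 FPKM (log2 fold change 1.43). Oaz1, an inhibitor of ornithine decarboxylase, rose from 314 ± 89.6 to 839 ± 262 FPKM (log2 fold change 1.40, adjusted p = 5.7e-04). Ppan, which acts in ribosome assembly, and Nsun5, an RNA methyltransferase, rose with log2 fold changes of 1.26 and 1.14. The other 7 were Taf1d, Tti2, Cyb5d1, Aaas, Sec24a, Armc6 and Krt10. The arms did not overlap for 9 of the 12 genes, and 5 are marked significant in the authors' deposited table. Ppan, Taf1d and Sec24a host snoRNA genes, Sec24a is marked as a failed estimate by the authors, and Taf1d and Sec24a did not pass against a minimum fold of 1.2. The Taf1d row is 1 of 12 at its locus. Another of these, snoU2_19, had a log2 fold change of 3.98, from 0.199 ± 0.343 to 55.5 ± 53.1 FPKM. It lay above the control mean in 4 of the 6 knockdown libraries, and its log2 fold change in the authors' deposited table was 0.785. The call of snoU2_19 was lost against a minimum fold of 1.2 (treat adjusted p = 0.103). It was also lost without knockdown library 1 or 6 (limma adjusted p = 0.0516 and 0.0525).

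Rows with short-RNA names were higher in the knockdown arm. Among 217 rows with a snoRNA name, 96 rose and 5 fell, with a median log2 fold change of 1.17. Among 236 rows with another short-RNA name, 65 rose and 6 fell (median 0.63). Against the control mean, the median over snoRNA names was 1.145, 0.78, 1.33, 0.71, 0.95 and 1.92 in knockdown libraries 1 to 6, and that over other short-RNA names 0.22, 0.06, 0.44, 0, 0.19 and 0.99, both highest in knockdown library 6, which also had the highest mitochondrial share. Among the 9550 other rows with a protein-coding symbol, 878 rose and 2766 fell (median −0.07). The 12 largest rises taken by the rule for named genes all had a mean below 1 FPKM in the control arm, none above 1.32 FPKM in any control library, and 10 of them carry the name of a genomic clone. In the authors' deposited table the log2 fold change was 2.21 for AC131120.1, the largest of these rises (8.72 here). It was 1.35 for AL592465.1 (6.905 here). U6 rows XLOC_018380 and XLOC_001204 were among the 12 largest falls (log2 fold changes −3.97 and −3.78), the latter at −0.19 in the authors' table. Over all rows tested, 5 were at 0 in all control and above 0 in all knockdown libraries, and 6 the other way. AL662835.1 (chromosome 11, 119097964 to 119098034) is listed at 0.258, 0, 0.291, 0, 0.119 and 0 FPKM in control libraries 1 to 6 and at 97.0, 97.0, 61.3, 0, 0 and 32.3 FPKM in knockdown libraries 1 to 6. AC113178.1 is listed at 0 in all control libraries and between 150.2 and 203 FPKM in the knockdown libraries, and AC170189.1, marked as a failed estimate by the authors, between 169 and 434 FPKM in the control libraries and at 0 in all knockdown libraries. Short-RNA names took 37.97% ± 0.998 of summed FPKM in control and 41.9% ± 1.92 in knockdown libraries (SD, n = 6 each; exact permutation p = 0.00649, two-sided).

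**Figure D2:**
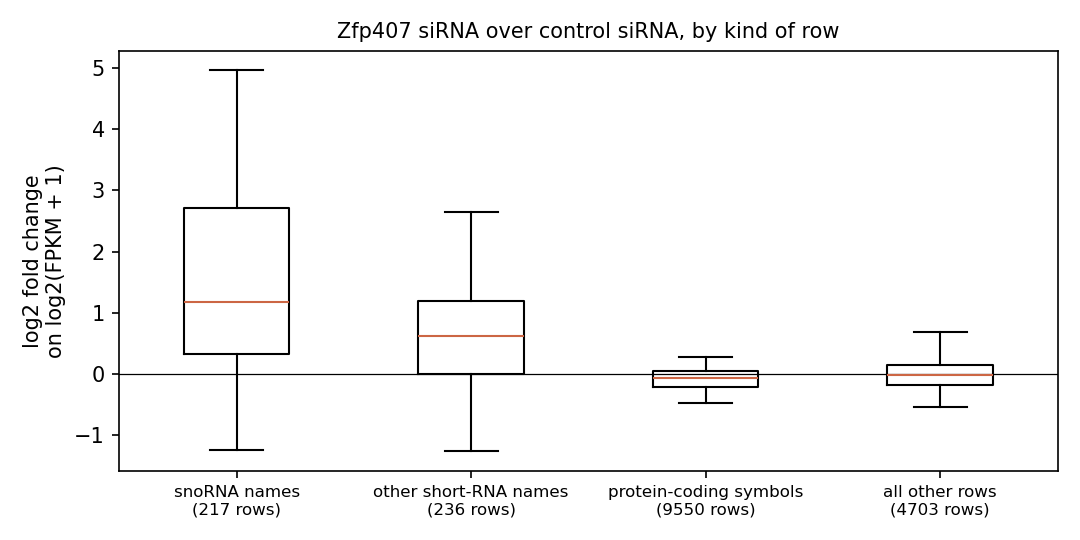
Log2 fold change on the log2(FPKM + 1) scale (vertical axis) of the rows tested, Zfp407 siRNA over control siRNA, for 4 kinds of row (horizontal axis). Boxes span the quartiles with the median as a line, and whiskers run from the 5th to the 95th percentile; the medians are 1.17 for snoRNA names, 0.63 for other short-RNA names, −0.07 for protein-coding symbols and −0.01 for all other rows.

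Of the 27 gene lists tested, 9 were lower and 6 higher in the knockdown arm than the remaining rows by camera. None of these 15 calls held with an estimated correlation, where 0 of the 27 lists had an unadjusted p under 0.05. Among 100 divisions of the 12 libraries into 6 and 6, the median number of lists called was 6 outside the real division. By fry, which asks whether a list moves on balance and compares it with no other genes, 14 lists were lower and 1 higher. The lists of oxidative phosphorylation, mitochondrially encoded transcripts, interferon-stimulated genes, ribosomal proteins and the proteasome did not pass by fry (adjusted p from 0.0523 to 0.927).

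Genes that PPARG activates in adipocytes fell on balance. Of 32 tested, 20 fell, 3 rose and 9 did not pass (21 lower and 4 higher adjusted over the list alone; camera adjusted p = 0.00166, and adjusted p = 0.761 with an estimated correlation). Retsat, a retinol saturase, fell from 115 ± 2.19 to 55.0 ± 3.42 FPKM (SD, n = 6 each; log2 fold change −1.05), Plin4, a lipid droplet coat protein, from 218 ± 17.1 to 112.6 ± 8.40 FPKM (log2 fold change −0.95), and Hsd11b1, which activates glucocorticoids, from 213 ± 10.6 to 124 ± 8.72 FPKM (log2 fold change −0.78). Fitm2, which promotes lipid droplet formation, rose from 52.6 ± 1.50 to 76.8 ± 5.01 FPKM (log2 fold change 0.54). Plin2 also rose (log2 fold change 0.58), while Fabp4, the fatty acid carrier of adipocytes, had a log2 fold change of −0.03 (adjusted p = 0.849); these 2 were chosen after their values were seen. The adipogenic transcription factors went both ways, with 6 falls and 4 rises among 23 tested, the same numbers adjusted over the list alone (camera adjusted p = 0.829). Nr1h3, the oxysterol receptor LXR alpha, fell from 51.5 ± 5.40 to 32.1 ± 3.12 FPKM (log2 fold change −0.66). Cebpa, a factor of terminal adipocyte differentiation, rose from 84.2 ± 2.68 to 111 ± 11.7 FPKM (log2 fold change 0.39, adjusted p = 4.5e-04). Cebpa did not pass against a minimum fold of 1.2, nor did Klf15 and Ebf1, which had fallen (log2 fold changes −0.32 and −0.28). Pparg itself, chosen after its value was seen, had a log2 fold change of −0.07 (adjusted p = 0.369).

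Insulin signalling and GLUT4 trafficking genes were lower as a list. Of 41 tested, 26 fell, 2 rose and 13 did not pass (27 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.00536, and adjusted p = 0.761 with an estimated correlation). With centring 19 fell and 2 rose, and after quantile normalization 16 fell and 3 rose. Cav1, the main protein of caveolae, fell from 1035 ± 63.3 to 670.5 ± 74.0 FPKM (SD, n = 6 each; log2 fold change −0.63), and Sort1, the sorting receptor of GLUT4 vesicles, from 102.5 ± 4.53 to 71.9 ± 4.97 FPKM (log2 fold change −0.51). Ralgapa2, a GTPase-activating protein subunit whose row the authors marked as failed, had a log2 fold change of −0.80. Sh2b2, an adaptor of the insulin receptor, rose from 38.5 ± 2.12 to 56.3 ± 2.85 FPKM (log2 fold change 0.54). For hexose transport and glycolysis, 11 of 28 genes fell and 2 rose, 1 of them Pygl, the same numbers adjusted over the list alone (camera adjusted p = 0.136). Pfkfb1, a regulator of phosphofructokinase, fell from 34.1 ± 1.08 to 18.3 ± 1.13 FPKM (log2 fold change −0.86), and Pdk1, which inhibits pyruvate dehydrogenase, from 187 ± 5.86 to 117.0 ± 9.54 FPKM (log2 fold change −0.68). Pfkm had a log2 fold change of −0.30, which did not pass against a minimum fold of 1.2. With centring 6 fell and after quantile normalization 7. The glycolysis list passed without a filter on low values (adjusted p = 0.0225), without knockdown library 4 (adjusted p = 0.0172) and by fry (adjusted p = 0.0290).

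Lists of lipid metabolism were lower. In fatty acid and triglyceride synthesis, 19 of 31 genes fell and 4 rose (20 and 5 adjusted over the list alone; camera adjusted p = 0.00345, and adjusted p = 0.761 with an estimated correlation). Fads2, a fatty acid desaturase, fell from 101.8 ± 4.92 to 53.3 ± 6.56 FPKM (SD, n = 6 each; log2 fold change −0.93), and Acss2 and Acly, which supply acetyl-CoA, fell with log2 fold changes of −0.83 and −0.57. Agpat9, a glycerol-3-phosphate acyltransferase, rose from 72.4 ± 1.17 to 121.5 ± 5.30 FPKM (log2 fold change 0.74). In lipolysis and lipid droplets, 12 of 18 genes fell and 2 rose (12 and 3 adjusted over the list alone; camera adjusted p = 0.0318, and adjusted p = 0.761 with an estimated correlation). Its most significant members were Plin4, Fitm2 and Cav1, given above, and Aqp7, a glycerol channel, which fell from 29.95 ± 2.69 to 15.5 ± 2.48 FPKM (log2 fold change −0.92). This list did not pass with the filter at a mean FPKM of 5 (adjusted p = 0.0616) or over protein-coding rows alone (adjusted p = 0.152).

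Genes of fatty acid oxidation and peroxisomes fell in 19 of 28 cases and rose in 2 (20 and 2 adjusted over the list alone; camera adjusted p = 7.4e-04, and adjusted p = 0.761 with an estimated correlation). Acadvl, the first enzyme of very long chain oxidation, fell from 195 ± 5.85 to 126 ± 2.49 FPKM (SD, n = 6 each; log2 fold change −0.62). Cpt2 and Slc25a20, which carry acyl groups into mitochondria, fell with log2 fold changes of −0.70 and −0.49, and Cat, the peroxisomal catalase, with −0.53. In sterol synthesis and SREBP2 targets, 16 of 22 genes fell and none rose, the same numbers adjusted over the list alone (camera adjusted p = 2.1e-05, and adjusted p = 0.761 with an estimated correlation). Insig1, a sterol sensor, fell from 276 ± 21.8 to 157 ± 26.8 FPKM (log2 fold change −0.82), and the synthesis enzymes Nsdhl and Cyp51 fell with log2 fold changes of −0.68 and −0.66. In the tricarboxylic acid cycle, 11 of 20 genes fell and none rose (12 and 1 adjusted over the list alone; camera adjusted p = 0.0171, and adjusted p = 0.768 with an estimated correlation). With centring or quantile normalization 1 rose. Pdhb and Dlat, of the pyruvate dehydrogenase complex, fell with log2 fold changes of −0.60 and −0.58, Suclg2 with −0.48 and Ogdh with −0.43, the last of which did not pass against a minimum fold of 1.2.

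**Figure D3:**
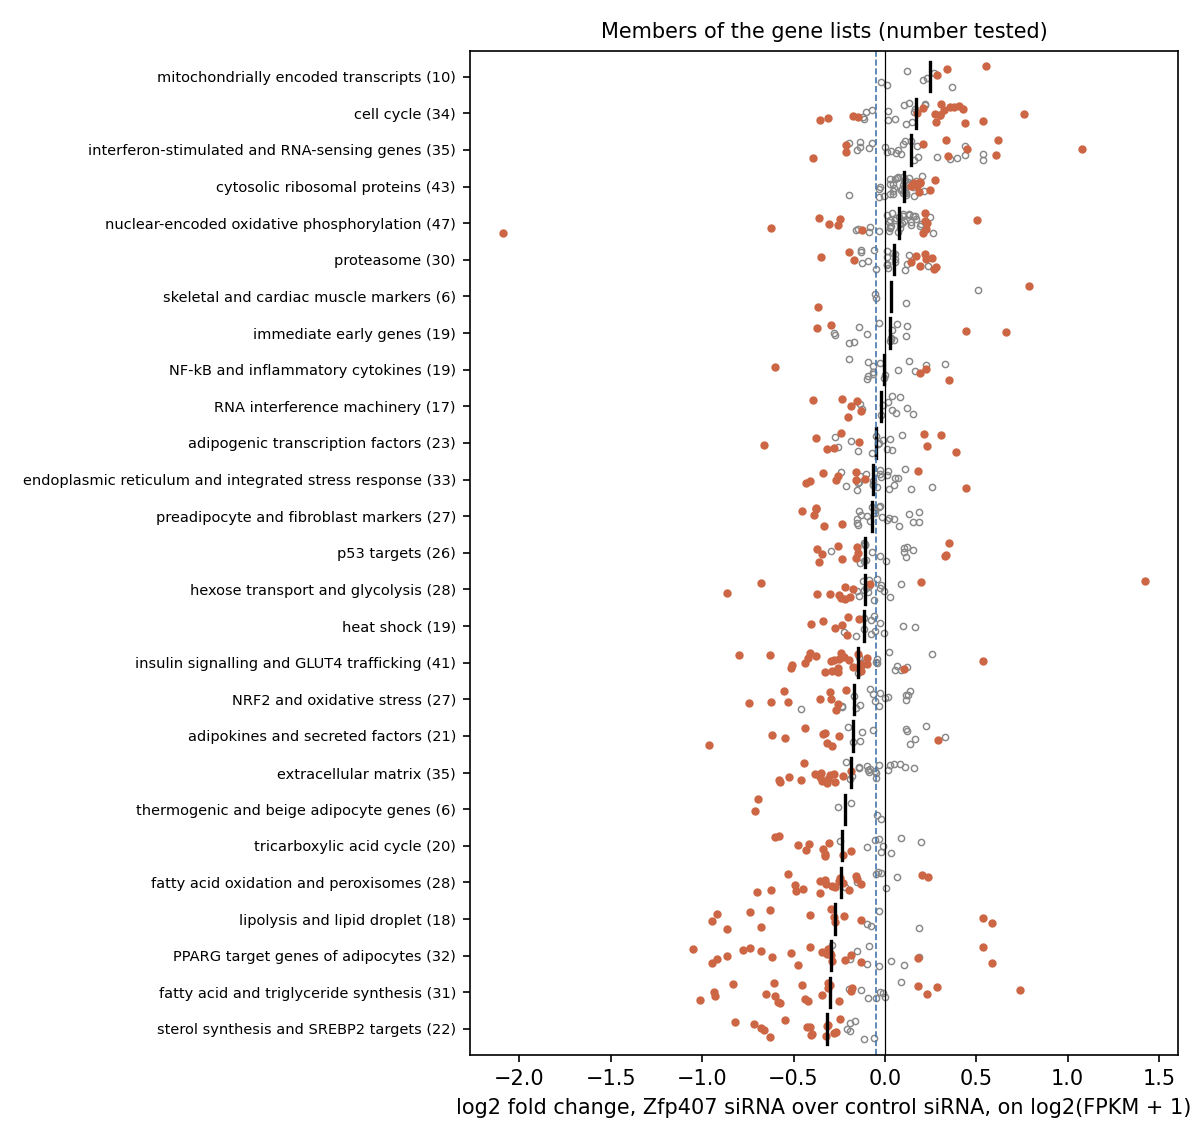
Log2 fold change on the log2(FPKM + 1) scale (horizontal axis) of each member of the 27 gene lists tested (vertical axis, number of members in brackets). Filled points passed the threshold, open points did not, black bars are list medians and the dashed line is the median of all 14706 rows (−0.05); list medians run from −0.32 for sterol synthesis to 0.25 for mitochondrially encoded transcripts.

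Oxidative phosphorylation was not lower as a list, although 2 complex I genes were among the largest falls. Of 47 nuclear-encoded genes, 6 rose, 7 fell and 34 did not pass, the same numbers adjusted over the list alone, and the median log2 fold change was 0.08 with a mean of 0.00 (camera adjusted p = 0.0355 towards higher values, and adjusted p = 0.802 with an estimated correlation). With centring, and after quantile normalization, 13 rose and 6 fell. Beside Ndufa1, Ndufs1 and Ndufv1 fell (log2 fold changes −0.62 and −0.26, the first from a row the authors marked as failed), and Cycs, cytochrome c, rose from 134 ± 13.3 to 191 ± 27.7 FPKM (SD, n = 6 each; log2 fold change 0.50). Ndufv1 and Cycs did not pass against a minimum fold of 1.2. The call of this list was lost without a filter (adjusted p = 0.127), with array weights (adjusted p = 0.184), without control library 2, 3 or 4 (adjusted p = 0.0881, 0.0564 and 0.0728) and without knockdown library 4, 5 or 6 (adjusted p = 0.0547, 0.115 and 0.113). Of 10 transcripts encoded in the mitochondrion, 3 rose and none fell (7 and 0 adjusted over the list alone; camera adjusted p = 0.00397, and adjusted p = 0.761 with an estimated correlation). With centring 7 rose and after quantile normalization 2. The ribosomal RNAs mt-Rnr2 and mt-Rnr1 had log2 fold changes of 0.56 and 0.34 and mt-Co1 of 0.29, of which none passed against a minimum fold of 1.2. The call of mt-Co1 was also lost without a filter (adjusted p = 0.209) and after quantile normalization (adjusted p = 0.104). For mt-Co2 the log2 fold change was 0.27 (adjusted p = 0.0534), and it passed without knockdown library 2 (adjusted p = 0.0163) or 4 (adjusted p = 0.0345) and in 5 other alternatives. Knockdown library 6, with 32.8% of its summed FPKM on the mitochondrial chromosome, was the highest in this measure, and the mean share did not differ between arms (exact permutation p = 0.591, two-sided).

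Extracellular matrix genes fell in 16 of 35 cases and rose in none (17 and 0 adjusted over the list alone; camera adjusted p = 0.0232, and adjusted p = 0.769 with an estimated correlation). After quantile normalization 10 fell. Col4a2, a basement membrane collagen, fell from 149 ± 9.07 to 100.3 ± 8.47 FPKM (SD, n = 6 each; log2 fold change −0.57), and Sparc, Col15a1 and Col5a2 had log2 fold changes of −0.35, −0.52 and −0.34, which did not pass against a minimum fold of 1.2. The matrix list did not pass without knockdown library 6 (adjusted p = 0.0698), with the filter at a mean FPKM of 5 (0.0626), with array weights (0.0682) or over protein-coding rows alone (0.0803). Of 27 preadipocyte and fibroblast markers, 6 fell and none rose (3 and 0 adjusted over the list alone; camera adjusted p = 0.686), but with centring 4 fell and 2 rose, and after quantile normalization 4 fell and 1 rose. The most abundant of them were Vim, at 1369 ± 91.1 and 1355 ± 133 FPKM (log2 fold change −0.02, adjusted p = 0.860), and Col3a1, at 1323 ± 58.5 and 1131 ± 135 FPKM (log2 fold change −0.23, adjusted p = 0.0326). Col3a1 did not pass without a filter (adjusted p = 0.0526), with centring (0.0655), after quantile normalization (0.0535), against a minimum fold of 1.2, without control library 1, 4 or 5 (0.0527, 0.0706 and 0.0588), or without knockdown library 3, 4 or 5 (0.0516, 0.0501 and 0.0565). Few markers of other cell types reached the level for testing. Of 2 macrophage and leukocyte markers tested, Lyz1 rose from 1.52 ± 0.172 to 2.10 ± 0.372 FPKM and Cd14 was at 3.41 ± 0.293 and 3.25 ± 0.455 FPKM. The single endothelial marker tested, Vwf, was at 1.37 ± 0.143 and 1.77 ± 0.265 FPKM (adjusted p = 0.0313), and did not pass without control library 1, 3, 5 or 6 (adjusted p = 0.052, 0.0531, 0.0649 and 0.0555) or knockdown library 1, 2, 3 or 6 (adjusted p = 0.0693, 0.0501, 0.0661 and 0.0542). Nor did Vwf pass with a block by column number (limma adjusted p = 0.0686). Of 6 muscle markers, Mb rose and Des fell (log2 fold changes 0.79 and −0.37; camera adjusted p = 0.546), 1 of each adjusted over the list alone, and none of 3 osteoblast and chondrocyte markers passed, with Spp1 at 45.1 ± 2.96 and 49.5 ± 8.55 FPKM and Sox9 at 8.10 ± 0.313 and 7.79 ± 0.866 FPKM. Lyz1, Vwf, Mb and Des did not pass against a minimum fold of 1.2.

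Cell cycle genes rose in 15 of 34 cases and fell in 4 (16 and 4 adjusted over the list alone; camera adjusted p = 3.7e-04, and adjusted p = 0.761 with an estimated correlation), at low levels. The replication helicase genes Mcm5, Mcm2 and Mcm3 rose, Mcm5 from 1.70 ± 0.283 to 3.58 ± 0.573 FPKM (SD, n = 6 each; log2 fold change 0.76) and the other two with log2 fold changes of 0.30, while Cdk2 fell (−0.15); of these, Mcm5 alone passed against a minimum fold of 1.2. With the filter at a mean FPKM of 5 the list did not pass (adjusted p = 0.287). Interferon-stimulated and RNA-sensing genes rose in 7 of 35 cases and fell in 3 (5 and 3 adjusted over the list alone; camera adjusted p = 0.0101, and adjusted p = 0.769 with an estimated correlation). Cxcl10, a chemokine, rose from 1.79 ± 0.933 to 4.84 ± 1.62 FPKM (log2 fold change 1.08), Rtp4 and Xaf1 had log2 fold changes of 0.62 and 0.33, and Gbp2 one of −0.21; the last 3 did not pass against a minimum fold of 1.2. The rows of Cxcl10 and of Art3, which fell, share 1 locus, whose reads the authors' estimation had to divide. The interferon list did not pass without knockdown library 6 (adjusted p = 0.0682) or with the filter at 5 (adjusted p = 0.0741).

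Genes of the NRF2 and oxidative stress list fell in 10 of 27 cases and rose in none, the same numbers adjusted over the list alone (camera adjusted p = 0.0408, and adjusted p = 0.769 with an estimated correlation). With centring, and after quantile normalization, 1 rose. The glutathione transferases Gstm1 and Gstm2 fell, from 144.5 ± 5.88 to 86.1 ± 6.11 and from 136.5 ± 4.57 to 88.4 ± 7.87 FPKM (SD, n = 6 each; log2 fold changes −0.74 and −0.63), and Sod3 had a log2 fold change of −0.36, which did not pass against a minimum fold of 1.2. This call was lost without control library 6 (adjusted p = 0.0604), without knockdown library 1, 2 or 3 (adjusted p = 0.0938, 0.0823 and 0.0719), with the filter at 5 (adjusted p = 0.0741), with a block by column number (adjusted p = 0.0596) and over protein-coding rows alone (adjusted p = 0.123). Of 43 cytosolic ribosomal protein genes, 8 rose and none fell (2 and 0 adjusted over the list alone; camera adjusted p = 4.9e-05, and adjusted p = 0.768 with an estimated correlation). With centring 16 rose and none fell, and after quantile normalization 5 rose and 1 fell. These changes were small, with log2 fold changes of 0.25 for Rpl24, whose row the authors marked as failed, 0.19 for Rpl19 and 0.18 for Rplp0, and the list did not pass after quantile normalization (adjusted p = 0.0650), nor did Rplp0 and Rpl19. Of 30 proteasome genes, 8 rose and 3 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.0297, and adjusted p = 0.769 with an estimated correlation). Psma2 and Psmd2 had log2 fold changes of 0.27 and 0.17, and Psmc5, whose row shares its locus with a U6 row that rose, and Psmd8 of −0.35 and −0.20. The proteasome call was lost without a filter (adjusted p = 0.0597), without control library 2 (adjusted p = 0.121) and without knockdown library 3 (adjusted p = 0.0574). None of the ribosomal and proteasome genes named passed against a minimum fold of 1.2.

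The remaining lists did not pass by camera. Adipokines and secreted factors had 9 falls and 1 rise among 21 genes (10 and 1 adjusted over the list alone; camera adjusted p = 0.195, fry adjusted p = 1.2e-04), and thermogenic and beige adipocyte genes 2 falls among 6 (3 adjusted over the list alone; camera adjusted p = 0.0700). Heat shock genes had 7 falls and no rise among 19 (camera adjusted p = 0.0700), endoplasmic reticulum and integrated stress response genes 8 falls and 2 rises among 33 (0.546), p53 targets 8 falls and 3 rises among 26 (0.750), and RNA interference machinery 6 falls and no rise among 17 (0.699). NF-kB and inflammatory cytokine genes had 3 rises and 1 fall among 19 (camera adjusted p = 0.287), and immediate early genes 2 of each among 19 (0.617). The balance of p53 targets moved to 5 falls and 5 rises with centring and after quantile normalization. With centring, falls in the stress response list were 5, rises among adipokines 3 and rises among heat shock genes 1. After quantile normalization, 2 heat shock genes and 1 RNA interference gene rose. The mean log2 fold change had the other sign than the median for NF-kB genes (mean 0.02, median −0.01; test towards higher values) and for immediate early genes (mean −0.01, median 0.03; test towards higher values). The thermogenic list passed without knockdown library 4 (adjusted p = 0.0471), with array weights (0.0432), without rows marked as failed (0.0411) and by fry (2.0e-04). The heat shock list passed without knockdown library 4 or 5 (adjusted p = 0.0412 and 0.0356), without a filter (0.00524), with a block by column number (0.0489) and by fry (0.00546), and p53 targets passed by fry (0.0388). Adjusted over the list alone, heat shock and RNA interference genes kept 7 and 6 falls, stress response genes 7 falls and 2 rises, p53 targets 8 and 4, NF-kB genes 1 fall and 2 rises, and immediate early genes 2 of each.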

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

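The limits on outlying libraries were applied to 234 groups of 6 values, over the named genes and 3 measures of whole libraries. 14 values lay apart from the other 5 of their group by more than the 95% limit of Dixon's ratio (the gap to the nearest value over the whole range), where chance gives about 1 in 20 groups, or 11.7. The tests weighed below were all chosen after the results they bear on had been seen.

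Control library 2 held 5 of the 14. Its U6 value of 31.9 FPKM stood above the others of 13.9 to 16.0 (ratio 0.884), and its values were lowest for Tbcd (19.9 against 21.7 to 22.5 FPKM, ratio 0.675), Art3 (34.1 against 46.6 to 52.9 FPKM, ratio 0.663), Nr1h3 (41.2 against 50.1 to 55.4 FPKM, ratio 0.631) and Cav1 (916 against 1031 to 1088 FPKM, ratio 0.666). Control library 3 was highest for Coq4 (20.8 against 13.3 to 15.9 FPKM, ratio 0.657), and control library 6 lowest for Fads2 (92.4 against 102.2 to 107.1 FPKM, ratio 0.667).

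In the knockdown arm, library 2 was highest for AC132367.1 (40.1 against 18.7 to 23.0 FPKM, ratio 0.801) and lowest for Nr1h3 (26.4 against 31.6 to 34.7 FPKM, ratio 0.626). Library 4 was highest for Aqp7 (20.3 against 13.5 to 15.7 FPKM, ratio 0.675) and Des (17.0 against 11.2 to 13.3 FPKM, ratio 0.644), and it held the single value above 0 of AC122775.1, 9.8e-04 FPKM (ratio 1). The fall of AC122775.1 did not pass without control library 3 or 4 (limma adjusted p = 0.052 and 0.0541, against 0.0248 with all libraries). Library 6 was lowest for Cat (186 against 211 to 222 FPKM, ratio 0.689) and Col15a1 (60.6 against 82.0 to 91.8 FPKM, ratio 0.684).

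More rows were lower than higher in the knockdown arm, 3648 against 1712, and chance can be excluded for the number of calls, since 1 of 100 divisions of the 12 libraries, the real one with 5360, called as many and the highest other called 1. The scaling of whole libraries stays open, since centring, which itself moves the balance, left 57.7% of calls lower (3146 against 2307), and between 56.8% and 59.6% when each library was also left out. Gene length and GC content were nearly unrelated to the fold change across protein-coding rows (rank correlations −0.0018 and −0.038). The worth of 1 read, which the authors' values fix per arm, stays open: of the 161 low rows where it differed, 34.2% had a lower worth in the knockdown libraries, which goes against the excess in those rows but says nothing of rows with higher levels. An effect of the knockdown, or of unintended siRNA targets, stays open, as untested.

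Whether the rise of snoRNA and other short-RNA rows comes in part from how very short rows were estimated could not be decided. Rows of up to 140 bases without a short-RNA name and with a locus of their own were also higher, by 0.27 in median log2 fold change against longer rows of up to 400 bases. The sorting was by name alone, and rows with clone names, such as AL592465.1 (79 bases), were among them. If such rows hold short RNAs, a change in short RNA itself would raise them too. The lowest non-zero values of the arms were over 4-fold apart in 17.4% of 420 very short rows, against 4.89% of 368 rows between 2 sets of control libraries, a difference of 12.5 percentage points. More transcription of the protein-coding genes that host snoRNAs, taken as a set, is argued against by the upper quartile of their log2 fold changes, 0.10, which lies far below the snoRNA median of 1.17. Hosts were not matched to the snoRNA rows that rose, and non-coding hosts were left out. The quartile therefore says nothing of single hosts, of which Ppan, Taf1d and Sec24a rose. A different recovery of short RNA in the knockdown arm, or an effect of the knockdown on these RNAs, would look alike in this table and was not tested.

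After centring, the 114 members of 5 lipid lists had a median log2 fold change of −0.25, against −0.29 without it, and an upper quartile of −0.095. These lists had already been called lower than the other rows, which a shift of whole libraries hardly alters. The values show that centring took away little of the fall, but they are no independent test of scaling. A lower share of adipocytes in the knockdown cultures would raise preadipocyte and fibroblast markers, of which 6 were called lower and none higher without rescaling but 4 lower and 2 higher with centring, so this explanation stays open. It would also lower adipocyte genes alike, and of the 32 PPARG target genes, 28.1% (exact 95% interval 13.8% to 46.8%) lay further from the list median than their error and the arm-wide term allow, a share too uncertain to decide, against a bound reset after it was seen. For the number of lists called over all themes, 4 of 100 divisions gave as many as the real 15, the highest other gave 16, and no list was called with an estimated correlation, so the share under 0.05 is weak ground for excluding chance. An effect of the knockdown on these genes stays among the open explanations, as untested.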

How the results depend on the processing

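The count of rows called stayed within 1.5 times of 5360 in each alternative but limma's treat with a minimum fold of 1.2, chosen after seeing the data, which called 856 (313 higher, 543 lower); a stricter question is asked there. Over protein-coding rows alone, also added later, fewer rows were tested and 929 were higher. Leaving out each library in turn gave 4782 to 5517 calls, and no row called in both the reported fit and any alternative changed sign. Zfp407 stayed called in all 11 other alternatives that tested it (log2 fold change −0.64 to −0.21, mostly by the pseudocount) and in all 12 fits without 1 library (−0.50 to −0.44). The filter at a mean FPKM of 5 removed it. Slc2a4 stayed called without any 1 library (−0.26 to −0.19) and in all other alternatives but the minimum fold of 1.2, where its log2 fold change of −0.22 did not pass (adjusted p = 1; range over alternatives 0.00186 to 1). The number of lists called, 9 lower and 6 higher, fell to 0 lower and 0 higher with camera at an estimated correlation; fry, which does not compare a list with other genes, called 14 lower and 1 higher. Without 1 library, 8 to 12 lists were lower and 4 to 6 higher. Among the 112 other named genes, the log2 fold change of Vim, never called, reversed with centring (0.0153) and ran from −0.053 to 0.0146 without 1 library, above 0 without control library 3 or knockdown library 3 or 6. The direction of the uncalled list of adipogenic transcription factors reversed with the filter at 5 (adjusted p = 0.870), quantile normalization (0.992) and protein-coding rows alone (0.846), and without knockdown library 3 (range without 1 library 0.693 to 0.989), as did that of p53 targets over protein-coding rows alone (0.887). The cause of these reversals was not tested. Of the calls of the other named genes, the minimum fold ended 40, quantile normalization 5 and each other alternative 0 to 2. Both pseudocounts and centring changed no list call. Camera compares a list with other rows, so a shift common to a whole library largely cancels there. Robust eBayes and the minimum fold do not enter camera, so list calls could not differ under them.

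The replicate block by the number in the column name, chosen after seeing the data, called 5700 rows (1876 higher, 3824 lower). Deviations of same-numbered libraries correlated by −0.06, 0.11, 0.09, 0.05, 0.03 and 0.20, and libraries 2, 3 and 6 but not 1, 4 and 5 correlated best with their own number, so the number was not read as a pairing. The planned block by label number, the 3-group fit, and all results for a single siRNA or between the siRNAs were not run because the columns do not show the siRNA. Depth in reads is unknown, and the worth of 1 read differs between arms in part of the low rows.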

Other observations

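The groups here were chosen from gene symbols after the table of all genes had been seen, and all of their tests are of that kind. Zinc finger genes named Zfp with a number, the naming family of Zfp407, rose more often than they fell. Of 283 tested, 46 rose and 27 fell, with a median log2 fold change of 0.03 (camera adjusted p = 0.00459, and adjusted p = 0.162 with an estimated correlation), while Zfp407 itself fell. With centring 60 rose and 12 fell (median 0.06), and after quantile normalization 50 rose and 19 fell (median 0.04). Mitochondrial carriers of the Slc25a family moved the other way, with 18 falls and 2 rises among 35 genes (median −0.13; camera adjusted p = 0.0290, and adjusted p = 0.339 with an estimated correlation). One of the falls was Slc25a1, which exports citrate for fatty acid synthesis, from 294 ± 14.1 to 188 ± 23.9 FPKM (SD, n = 6 each; log2 fold change −0.65, limma adjusted p = 4.1e-05). Mitochondrial ribosomal protein genes had 10 falls and 3 rises among 74, but 9 falls and 10 rises with centring (camera adjusted p = 0.826). Protein-coding genes that host a snoRNA had 38 falls and 26 rises among 192, but 33 and 36 with centring (camera adjusted p = 0.653).

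Single genes outside the rule for named genes also fell. Commd10, of the COMM domain family that acts in endosomal sorting, fell from 14.7 ± 0.703 to 6.71 ± 0.630 FPKM (SD, n = 6 each; log2 fold change −1.03, limma adjusted p = 5.4e-08), and 3 of the 8 COMM domain genes tested fell while none rose (camera adjusted p = 0.239). Scd1, the stearoyl-CoA desaturase of lipid synthesis, fell from 2972 ± 207 to 1499 ± 332.5 FPKM (log2 fold change −1.01, adjusted p = 8.6e-05). Lep, the gene of leptin, fell from 9.80 ± 0.993 to 4.61 ± 1.12 FPKM (log2 fold change −0.96, adjusted p = 1.0e-04), and Tbc1d4, which holds GLUT4 vesicles back in the absence of insulin, from 12.5 ± 1.50 to 8.52 ± 1.69 FPKM (log2 fold change −0.52, adjusted p = 0.00454). All 4 genes were chosen after their values were seen.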
